A study of Mus musculus with 6 samples.

How the data were processed

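Regulatory T cells were sorted by flow cytometry as CD4+CD25+YFP+ cells from spleen and lymph nodes of female C57BL/6 mice aged 7 weeks, per the labels, and their mRNA was sequenced on an Illumina instrument after library preparation with the NEBNext Ultra kit. The wild-type mice (WT) carried a Foxp3-driven Cre with YFP on 1 of their X chromosomes, and the conditional knockout mice (cKO) carried in addition floxed alleles of Tkt. The design text gives 3 mice per group and does not state whether a library pools animals, so the p-values measure the spread between these 6 libraries. Groups and replicate numbers were taken from the titles of the samples.

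The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.16.1 and the mouse build mm10, with no role or order. The values used here are the estimated counts per gene that the authors deposited for each library, which are not normalized. About 46% of the values in each library were not whole to within 0.01 (45.4% to 46.3%), which whole-read counting does not give by default; how these fractions arose is not given in the sources used here. A second set of columns holds values that behave as FPKM, normalized by the authors per length and depth, as judged from the values and from gene lengths. The authors also deposited group means of both the estimated counts and the FPKM, which were not used.

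The table holds 18493 genes. Of these, 956 carry a BGI identifier with no gene name and take 2.11% to 2.33% of the reads of a library. Entrez identifiers of 17412 genes matched the RefSeq annotation of GRCm38.p6, the same build as mm10, from which coordinates were taken, counted from 1. A spreadsheet had turned 23 symbols into dates, and these were restored from the Entrez identifiers. Among genes with over 50 estimated reads, 2 pairs had identical values in all libraries. The 13 mitochondrially encoded genes of the respiratory chain were not analysed here.

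Estimated counts were rounded to whole numbers. In R 4.3.3, genes passing the filterByExpr function of edgeR 4.0.16 (minimum count 10) were kept, which left 12887 genes. Libraries were scaled by the trimmed mean of M values (TMM). Each gene was tested with edgeR's quasi-likelihood F test with the group as the only term, and p-values were adjusted by Benjamini-Hochberg over all genes tested; a gene was called at an adjusted p under 0.05. CPM values are counts scaled to library size after TMM. The standard error of a log2 fold change was derived from the F statistic. All tests were two-sided unless stated otherwise. The total was 17180577 to 18215168 estimated reads per library, and the common biological coefficient of variation was 16.7%. With 3 libraries against 3, an exact permutation test of a single value cannot give a two-sided p under 0.1, so single genes rest on the model fitted across genes.

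The comparison, its alternatives, the rule for naming genes and 29 gene lists were fixed before the data were examined. The lists cover central metabolism, DNA methylation, T cell states, signalling responses and 7 other cell types that the sort could hold, and 28 of them had at least 3 tested members. Lists were tested with camera of limma 3.58.1, with a preset inter-gene correlation of 0.01 and again with a correlation estimated per list, adjusted over the lists. The rotation test fry was an alternative. Named genes included Tkt, its paralogs Tktl1 and Tktl2, Foxp3, Il2ra, Ctla4, Il10, Ikzf2 and Tcf7. To these were added the 12 largest rises and 12 largest falls among called genes whose groups did not overlap and whose mean was at least 1 CPM in a group. Predicted gene models and antigen receptor segments were left out of that part. Of each list, up to 4 called members with the lowest p were named, or the member with the lowest p if none was called. Of each list of another cell type, the member with the highest mean CPM was added. Tktl2 was not analysed here, and some genes that the rule names are not reported here.

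The alternatives were DESeq2 1.42.0, limma-voom, other scaling factors, no filter or a stricter filter (CPM of at least 1 in at least 3 libraries), the replicate number as a block, robust empirical Bayes, the quasi-likelihood fit with the argument legacy set to TRUE, and each library left out in turn. Because legacy set to TRUE is the default in the edgeR version used, that alternative is the same fit as the reported one. The newer fit, with legacy set to FALSE, was at first run by mistake as the fit to report, and was replaced after its results had been seen because the default had been fixed beforehand. It was kept as an added alternative. Also added were a fit without WT2 and cKO1, the 2 libraries highest on the first principal component, and a fit with a score of immediate early genes as a covariate.

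The code was tested on simulated counts for cKO against WT, drawn from the means, dispersions and library sizes of these libraries. Among 12725 simulated genes tested with edgeR, 24.6% of 65 genes changed 1.5-fold were called with the right sign, as were 70.8% of 65 genes changed 2-fold and 90.9% of 66 genes changed 4-fold. Of 12504 unchanged genes, 10 were called. With DESeq2 the shares were 44.8%, 71.6% and 95.5%, and 39 of 12659 unchanged genes were called. The simulated genes were drawn independently, with no differences between libraries shared across genes. These shares and counts are therefore not error rates for the real libraries. No 2 libraries agreed within sampling noise: the lowest chi-square per degree of freedom between 2 libraries was 4.15, for WT1 and WT3.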

Results

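Transketolase, encoded by Tkt, is an enzyme of the non-oxidative branch of the pentose phosphate pathway, which exchanges sugar phosphates with glycolysis. Regulatory T (Treg) cells are CD4 T cells that restrain immune responses and depend on the transcription factor Foxp3. The study asked how Treg cells depend on this branch of metabolism. RNA was measured in CD4+CD25+YFP+ cells sorted from 3 WT and 3 cKO female mice. In the cKO mice, Tkt is deleted in cells that express Cre from the Foxp3 locus. Foxp3 lies on the X chromosome, so females with 1 copy of the Cre allele are mosaics, and the YFP+ sort takes the cells in which that allele is active. The WT libraries held 17715571, 17180577 and 17584289 estimated reads, and the cKO libraries 17709728, 18215168 and 17647866.

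Tkt stood at 126, 97.1 and 121 CPM in the WT libraries and at 52.5, 44.8 and 31.9 CPM in the cKO libraries. The group means were 115 ± 15.4 CPM (SD, n = 3) and 43.0 ± 10.4 CPM (SD, n = 3), and every cKO library lay below every WT library. The gene (Entrez 21881) spans positions 30549131 to 30574724 of chromosome 14 in mm10. Its fitted log2 fold change was -1.41 ± 0.19 (SE), and its adjusted p was 0.0516 in edgeR's quasi-likelihood test, just above the threshold of 0.05, so Tkt was not called. The adjusted p ranged from 2.4e-10 with DESeq2 to 0.217 without cKO2 over all alternatives, and 8 of 19 alternatives called it. The value counts reads over the whole gene, and the labels do not say which exons were floxed. The paralog Tktl1 was near the detection limit, at 0.975 ± 0.269 CPM in WT and 0.524 ± 0.116 CPM in cKO (SD, n = 3; adjusted p = 0.634).

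Most genes that passed the test were lower in cKO cells. Of 12887 genes, 27 were called, 26 of them lower and 1 higher in cKO cells, and 16 differed at least 2-fold. Klrg1, an inhibitory lectin-like receptor of differentiated effector lymphocytes, fell 15.2-fold, from 6.95 ± 0.713 to 0.453 ± 0.324 CPM (SD, n = 3; log2 fold change -3.93 ± 0.47 SE, adjusted p = 0.0449). Tigit, an inhibitory receptor of Treg and other T cells, fell from 45.6 ± 2.72 to 19.0 ± 2.12 CPM (log2 fold change -1.26 ± 0.10 SE, adjusted p = 0.0269). Icos, a costimulatory receptor, fell from 230.0 ± 20.4 to 131 ± 11.8 CPM (adjusted p = 0.0449). Wdfy4, known for its part in antigen cross-presentation by dendritic cells, was the only gene called higher and rose from 23.4 ± 2.99 to 48.5 ± 2.95 CPM (log2 fold change 1.05 ± 0.11 SE, adjusted p = 0.0444).

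**Figure D1:**
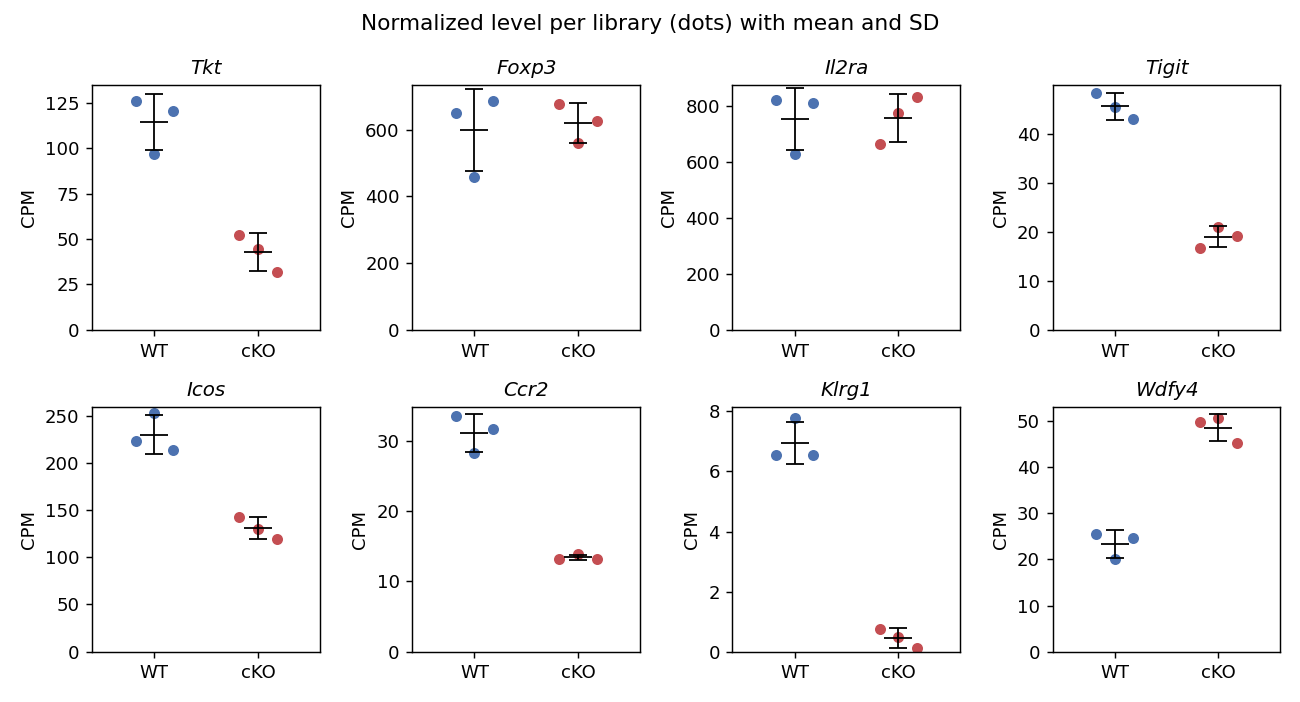
Normalized level in CPM (vertical axes from 0) of 8 genes in the 3 WT (blue) and 3 cKO (red) libraries, each dot a library, with the mean (horizontal bar) and SD (error bar, n = 3). Tkt, Tigit, Icos, Ccr2 and Klrg1 lie lower and Wdfy4 lies higher in all 3 cKO libraries than in any WT library, while the libraries overlap for Foxp3 and Il2ra.

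The other large falls covered several classes of protein. Slc7a10, a transporter of small neutral amino acids, fell 6.28-fold from 4.72 ± 0.253 CPM, and Magi1, a membrane scaffold protein, fell 5.0-fold from 26.3 ± 9.78 CPM (SD, n = 3). The calcium-binding proteins S100a4 and S100a11 fell 2.99-fold and 2.12-fold. Ttn, which encodes titin, fell 2.54-fold, Tox2, a transcription factor of the HMG-box family, fell 2.43-fold, and Nav2 fell 2.26-fold. Lilrb4a, an inhibitory immunoglobulin-like receptor, fell 2.84-fold, but its reads can be shared with a near-identical paralog and its value is uncertain. A gene listed as BGIG10090_39224, with no name in the table, fell 2.97-fold from 98.2 ± 17.5 CPM. The adjusted p-values of these 9 genes in edgeR's test lay between 0.0269 and 0.0474. The remaining 10 called genes that the naming rule did not reach had log2 fold changes from -2.79 to -0.67.

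Genes that mark Treg identity did not pass the test, although their mean level was lower in every cKO library. Foxp3 stood at 598 ± 122.7 CPM in WT and 620.4 ± 58.9 CPM in cKO (log2 fold change 0.05 ± 0.16 SE, adjusted p = 0.987). Il2ra, which encodes the CD25 chain used in the sort, stood at 755 ± 109.8 and 757 ± 85.7 CPM (log2 fold change 0.01 ± 0.13 SE, adjusted p = 0.9996). Ikzf2, encoding Helios, had a log2 fold change of -0.21 ± 0.09 (SE; adjusted p = 0.642). None of the 26 tested members of the identity list was called, their median log2 fold change was -0.06, and the list did not pass its test (camera, adjusted p = 0.166). Their mean log2 CPM was 7.79 to 7.83 in the cKO libraries, below the 7.87 to 7.90 of the WT libraries, and that of the 18 members taken as specific to Treg cells, a choice made after seeing the data, differed by -0.17 ± 0.007 (SE). Without WT2 the list was called lower (median -0.11, adjusted p = 0.0064), as it was without both WT2 and cKO1, a choice made after seeing the data (median -0.11, adjusted p = 0.0031), both with the preset correlation. With all libraries the adjusted p was 0.786 with an estimated correlation and 0.237 with fry. Adjusted over the list alone, Cd83, an activation marker, was lower (79.2 ± 12.6 to 43.9 ± 2.94 CPM) and the chromatin organizer Satb1 was higher (396 ± 25.1 to 522 ± 29.8 CPM).

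The genes of the effector phenotype and tissue homing of T cells fell together. The median log2 fold change of the 29 tested members was -0.48 (camera, adjusted p = 1.2e-46; adjusted p = 0.0115 with an estimated correlation; adjusted p = 0.0052 with fry). Over all genes, 5 members were called lower and none higher, and adjusted over the list alone 21 were lower and none higher. Ccr2, the receptor of the chemokine CCL2, fell from 31.1 ± 2.68 to 13.4 ± 0.392 CPM (adjusted p = 0.0269). Cxcr4, the receptor of CXCL12, fell from 331 ± 8.25 to 187 ± 8.23 CPM (adjusted p = 0.0269), and Itgb1, the integrin beta-1 chain, fell from 261 ± 23.6 to 147 ± 8.34 CPM (adjusted p = 0.0449). S100a11 and S100a4 were the other called members. The members lower over the list alone included the chemokine receptors Cxcr3, Ccr4, Ccr8 and Cxcr6, the adhesion molecule Cd44, and the transcription factors Maf, Irf4 and Batf. In 8 members no difference was called by either adjustment, among them Selplg, Vim and Crip1 with log2 fold changes of 0.07, -0.05 and -0.03.

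The list of suppressive effectors of Treg cells was lower as a group as well. It is not limited to suppressive molecules, as it also holds the costimulatory receptor Icos and the interleukin-33 receptor. The median log2 fold change of the 22 tested members was -0.75 (camera, adjusted p = 9.7e-28; adjusted p = 0.0115 with an estimated correlation; adjusted p = 0.0052 with fry). Over all genes, Tigit, Klrg1 and Icos were called lower, and adjusted over the list alone 10 members were lower and none higher. The further 7 were the cytokine Il10, Gzmb (granzyme B), Il1rl1 (the interleukin-33 receptor), Prdm1 (Blimp-1), Ebi3 (a subunit of interleukin-35), Fgl2 and Itgae (CD103). Il10 stood at 51.7 ± 11.2 CPM in WT and 22.3 ± 5.06 CPM in cKO (log2 fold change -1.21 ± 0.21 SE), with an adjusted p of 0.0978 over all genes. Ctla4 varied widely between libraries, from 753 to 1727 CPM in WT and from 492 to 977 CPM in cKO, and did not pass (log2 fold change -0.57 ± 0.37 SE, adjusted p = 0.826). Tgfb1 stood at 316 ± 71.8 and 321 ± 12.5 CPM (adjusted p = 0.994). Entpd1, Nt5e and Lag3 were not called by either adjustment (log2 fold changes -0.24, -0.23 and -0.42), and neither was Prf1 (0.52).

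**Figure D2:**
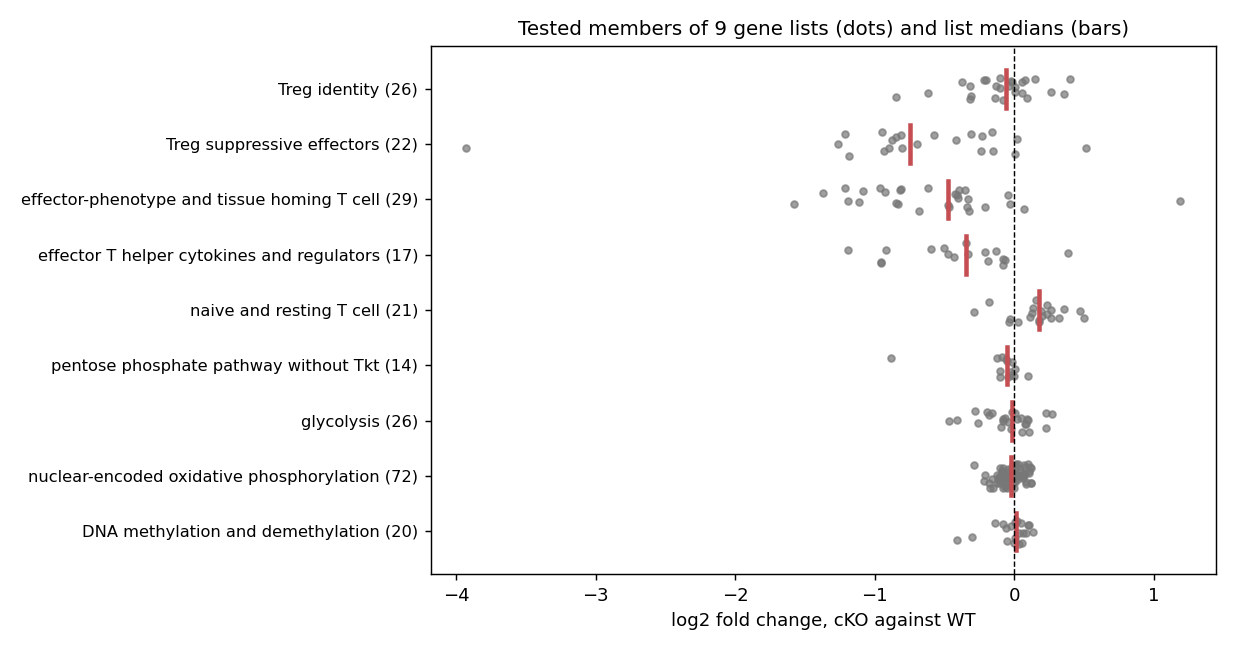
Fitted log2 fold change of cKO against WT (horizontal axis) for each tested member (grey dots, spread vertically for legibility) of 9 gene lists, with the number of members in brackets and the list median as a red bar. The medians lie at -0.75 for suppressive effectors and -0.48 for the effector-phenotype list, and between -0.06 and 0.01 for the identity, metabolic and DNA methylation lists shown.

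Other T cell programs passed the test with the preset correlation only. The list of T helper cytokines and regulators was lower (17 members, median log2 fold change -0.35, camera adjusted p = 8.7e-09), a call that was lost with an estimated correlation (adjusted p = 0.141). No member was called over all genes. Adjusted over the list alone, 4 members were lower, among them Rora, Ifng and Il1r1. Genes of naive and resting T cells were higher (21 members, median 0.18, camera adjusted p = 0.00017; adjusted p = 0.166 with an estimated correlation), with no member called by either adjustment. Lef1 had a log2 fold change of 0.32 ± 0.08 (SE; adjusted p = 0.304) and Tcf7 0.18 ± 0.13 (adjusted p = 0.853). Of the 21 naive and resting genes, 5 also stand in another list. The list of conventional CD4 T cell markers was higher as well (14 members, of which 7 are also in another list, median 0.13, adjusted p = 0.0403; adjusted p = 0.516 with an estimated correlation), and the call was lost without WT1 (adjusted p = 0.161) or without cKO3 (adjusted p = 0.245). Its most abundant member Dgka stood at 1507 ± 64.3 and 1574 ± 83.4 CPM.

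The remaining enzymes of the pentose phosphate pathway did not pass the test. None of the 14 tested members of the list without Tkt was called by either adjustment, and the median log2 fold change was -0.05 (camera, adjusted p = 0.420). Their mean log2 CPM was nevertheless lower in every cKO library, at 4.64 to 4.75 against 4.77 to 4.79 in the WT libraries. Taldo1, the transaldolase of the same branch, stood at 85.3 ± 0.300 and 85.7 ± 2.94 CPM, and G6pdx, the first enzyme of the oxidative branch, at 45.2 ± 1.69 and 43.5 ± 1.04 CPM. No other metabolic list passed either, and no member of any of them was called over all genes. The medians and camera adjusted p-values were -0.02 and 0.989 for glycolysis (26 members), 0.01 and 0.712 for the TCA cycle (28), and -0.02 and 0.561 for nuclear-encoded oxidative phosphorylation (72). They were -0.01 and 0.825 for fatty acid oxidation (27), 0.01 and 0.781 for fatty acid and sterol synthesis (30), and 0.01 and 0.555 for antioxidant and glutathione genes (33). For glutamine, serine and one-carbon metabolism (26) they were -0.02 and 0.825, and for nucleotide synthesis (29) -0.03 and 0.478. Adjusted over the list alone, the glutaredoxin Glrx was lower (59.0 ± 1.81 to 32.8 ± 5.53 CPM, adjusted p = 0.0572 over all genes). The members with the lowest p in the other lists had adjusted p-values above 0.3, with log2 fold changes of 0.27 for Pdk1, 0.23 for Me2, -0.17 for Uqcrh, 0.20 for Acaa1a, 0.24 for Mvd, -0.79 for Asns and -0.37 for Tyms. Fatty acid oxidation genes had a median below 0 but a mean and a camera direction above 0, and the antioxidant genes had the opposite signs.

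Genes of DNA methylation and demethylation did not pass the test. None of the 20 tested members was called by either adjustment, and the median was 0.01 (camera, adjusted p = 0.989), while the mean was -0.02. The member with the lowest p, Uhrf1, had a log2 fold change of -0.41 ± 0.28 (SE; adjusted p = 0.840). Dnmt1 stood at 152 ± 24.4 and 155 ± 16.2 CPM and Tet2 at 109 ± 17.1 and 103 ± 4.12 CPM in WT and cKO.

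Among the signalling lists, cell cycle genes were lower by the preset correlation only. The proliferation list had a median of -0.41 over 40 members (camera, adjusted p = 2.2e-06; adjusted p = 0.786 with an estimated correlation), no member was called by either adjustment, and the call was lost without cKO1, the library with the lowest score (adjusted p = 0.127). Prc1 had a log2 fold change of -0.74 ± 0.19 (SE; adjusted p = 0.304). The immediate early genes, which respond to T cell receptor signals, had a median of -0.11 over 31 members (adjusted p = 0.0494; adjusted p = 0.786 with an estimated correlation), and were called in 11 of 20 alternatives. The call was lost without WT2 (adjusted p = 0.744) or cKO3 (adjusted p = 0.900), and also with the stricter filter, with robust empirical Bayes, with limma-voom and without WT2 and cKO1 together. Klf6 had a log2 fold change of -0.55 ± 0.13 (SE; adjusted p = 0.233). The lists of interferon response (median 0.05, adjusted p = 0.242), unfolded protein response (-0.09, 0.166), hypoxia (0.03, 0.825) and apoptosis (-0.003, 0.555) did not pass. Without WT3 the interferon list was called higher (adjusted p = 0.0294), as it was without cKO2 (adjusted p = 0.0283), and the unfolded protein list was called lower without WT3 (adjusted p = 0.0302). In the interferon, unfolded protein and hypoxia lists, the members with the lowest p were Gbp3 (-0.28), Atf6 (-0.31) and Pdk1 (0.27), by log2 fold change, none of them called. The mean of the hypoxia list was below 0.

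Markers of other cell types differed between libraries. The 13 tested B cell markers were higher in cKO (median 0.90, camera adjusted p = 0.0118; adjusted p = 0.786 with an estimated correlation), with no member called, and the call was lost without cKO1 (adjusted p = 0.394) or cKO2 (adjusted p = 0.0626). Their summed level was 66.5, 111 and 71.7 CPM in WT and 127, 139 and 53.5 CPM in cKO, so that cKO3 lay below all WT libraries, while its mean log2 CPM over these markers (0.903) lay between those of WT1 (0.730) and WT3 (1.05). Cd74, the most abundant, stood at 47.9 ± 13.2 and 60.1 ± 26.8 CPM, and Bank1 had the lowest p (log2 fold change 0.92, adjusted p = 0.336) and was highest in cKO3. The 5 stromal and endothelial markers were higher (median 0.96, adjusted p = 0.0018; adjusted p = 0.624 with an estimated correlation; adjusted p = 0.113 with no low-count filter), at a like level in WT2 and the 3 cKO libraries. Pecam1, which T cells also express, stood at 195 ± 9.26 and 217 ± 15.95 CPM. The myeloid list did not pass (median 0.51, mean 0.59, camera direction down, adjusted p = 0.942), but was called higher without cKO3 (adjusted p = 0.011). Its called members Ccr2 and Cybb, the catalytic chain of the phagocyte NADPH oxidase (38.9 ± 3.30 to 22.7 ± 1.61 CPM, adjusted p = 0.0449), both fell. Ctss, its most abundant member, stood at 183 ± 14.3 and 176 ± 0.860 CPM. Erythroid markers (median 4.01, adjusted p = 0.0673; adjusted p = 0.786 with an estimated correlation) were high in cKO1 alone, where Hba-a1 stood at 83.6 CPM and Hbb-bs at 37.9 CPM. They were called higher in 5 of 20 alternatives, which were without cKO2 (adjusted p = 0.0023), without cKO3 (adjusted p = 0.001), with library size only, with no low-count filter and with the immediate early score as a covariate, the last chosen after seeing the data. Plasma cell markers (median 0.04, adjusted p = 0.555) and CD8 T and NK cell markers (median 0.23, camera direction down, adjusted p = 0.890) did not pass. The members named from those lists were Jchain (1.33), Eaf2 (0.04), Nkg7 (-0.66) and Cd8b1 (0.23), by log2 fold change, none of them called.

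**Figure D3:**
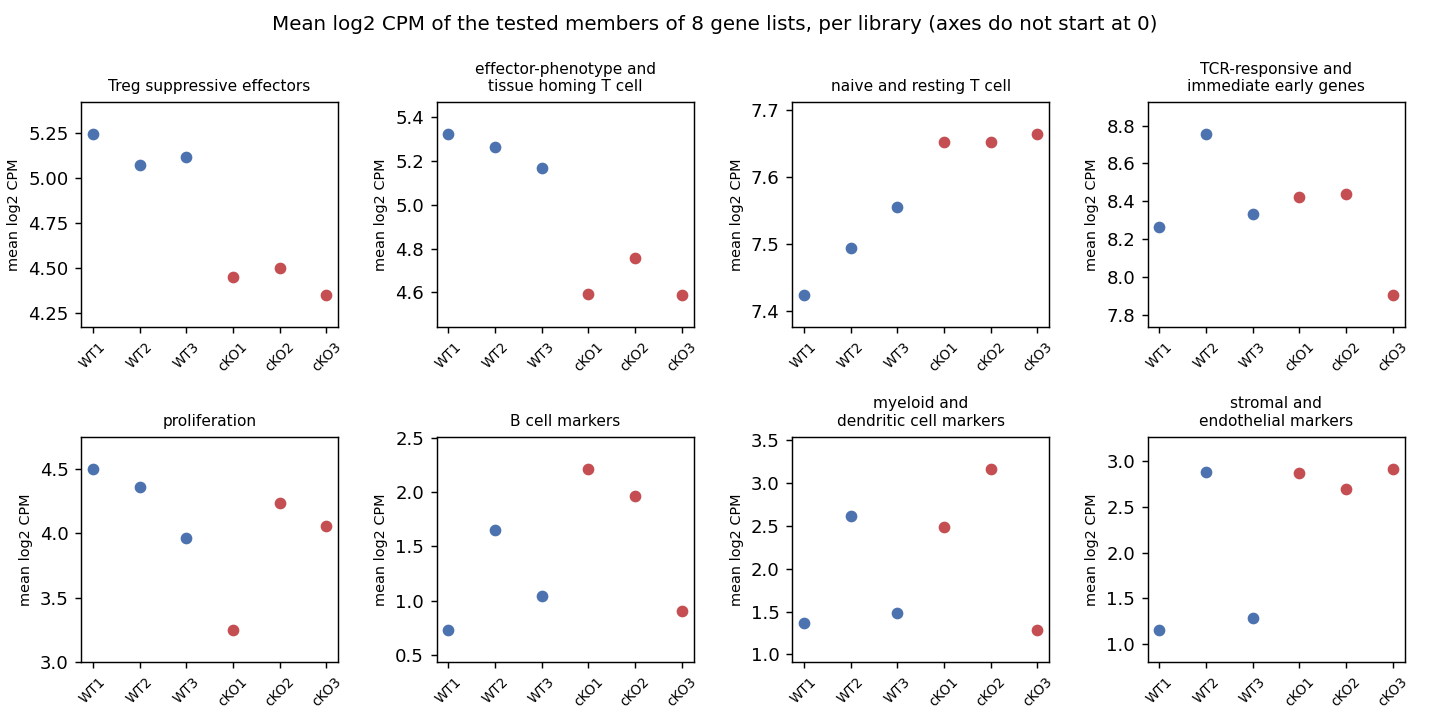
Mean log2 CPM of the tested members of 8 gene lists (vertical axes, not starting at 0) in each WT (blue) and cKO (red) library. The suppressive and effector-phenotype scores of the 3 cKO libraries lie below those of all WT libraries (4.35 to 4.50 against 5.07 to 5.24, and 4.59 to 4.76 against 5.17 to 5.32), while the B cell, myeloid and immediate early scores follow other divisions of the libraries.

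The count of called genes depended on which libraries were included. Leaving out WT1, WT3, cKO1, cKO2 or cKO3 left 0 genes called by edgeR's test (681 to 909 at an unadjusted p under 0.05, against 991 with all libraries), and leaving out WT2 left 30, of which 15 were among the 27. DESeq2 called 171 genes, 24 higher and 147 lower, including all 27. All 27 kept their direction in every alternative. The groups did not overlap for any of the 27, so leaving out libraries could hardly reverse them, and the kept direction adds no support. WT2 and cKO1 lay highest on the first principal component (36.1% of the variance), at 25.4 and 33.2. cKO2 followed at 8.11, and WT1, WT3 and cKO3 lay at -25.9 to -18.4. Hspa1a stood at 12.7 and 5.35 CPM in WT2 and cKO1, against 26.4 CPM (cKO2) to 163 CPM in the other libraries. Tnfaip3 stood at 4898 and 4612 CPM in WT2 and cKO1 against 1152 to 2332 CPM. Without WT2 and cKO1, a choice made after seeing the data, 71 genes were called (10 higher, 61 lower), 21 of them among the 27.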

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

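The fits without WT2 and cKO1, with an immediate early score as a covariate and with edgeR's newer quasi-likelihood form were chosen after seeing the data, the others before the data were examined. The fit with legacy set to TRUE is edgeR's default here and gave identical values. Counts are given in the order of all called genes, higher, lower and at least 2-fold, which were 27, 1, 26 and 16 as reported. They were 171, 24, 147 and 59 with DESeq2, 43, 2, 41 and 25 with no low-count filter, and 48, 2, 46 and 26 with robust empirical Bayes. Without WT2 and cKO1 they were 71, 10, 61 and 32, and with the immediate early score as a covariate 78, 19, 59 and 45. With each replicate left out in turn they ranged from 0 to 30, 0 to 4, 0 to 26 and 0 to 13. The genes called higher were 2 with library size only, with the stricter filter and with the newer quasi-likelihood fit, which called 31 genes in all. The total was 27 with RLE factors, 21 with upper-quartile factors and 19 with limma-voom. With the replicate block, 0 genes were called in all 4 counts (811 at an unadjusted p under 0.05), and the calls of Wdfy4 and of each falling gene were lost. Same-numbered libraries had correlations of their deviations from the group mean of -0.28, 0.06 and 0.26 (r across genes, genes not being independent replicates). Among the WT libraries, cKO1 deviated most alike with WT2 (r = 0.31). cKO2 and cKO3 deviated most alike with the WT library of the same number, by small margins (0.06 against 0.05 with WT1, and 0.26 against 0.24 with WT1). With deviations taken within groups of 3, these values do not decide whether the numbers pair the samples. The cause of these differences was not tested. Leaving out libraries or adding a term leaves fewer degrees of freedom, yet some of these fits called more genes than the 27 reported. They were 30 without WT2, 71 without WT2 and cKO1, and 78 with the covariate.

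The log2 fold change of Tkt lay between -1.68 and -1.24 in all fits, and its side of the threshold moved. It was past the threshold with DESeq2 (-1.41), library size only (-1.42), no filter (-1.41), the stricter filter (-1.41), robust empirical Bayes (-1.41), the newer quasi-likelihood fit (-1.41, adjusted p = 0.0473), without WT2 and cKO1 (-1.68) and with the covariate (-1.38). It was not past it with RLE or upper-quartile factors, limma-voom, the replicate block (adjusted p = 0.189) or any replicate left out (-1.58 to -1.24). The cause was not tested.

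Of 28 lists, 9 were called with the preset correlation, 2 with an estimated correlation and 2 with fry, in both cases the effector-phenotype and suppressive lists, which were called in all 20 alternatives. Of the other 7 lists called as reported, the T helper and naive lists were called in 18 of the 20, the stromal list in 17, proliferation in 16, conventional CD4 T cell markers in 15, B cell markers in 14 and immediate early genes in 11. The counts with each replicate left out ranged from 7 to 11. The medians of these lists ranged from -0.62 to -0.46 and from -0.80 to -0.59. The myeloid list, down and not called, turned to up and called with the replicate block (adjusted p = 0.0405), without cKO replicate 3 (adjusted p = 0.011, the lowest of a range up to 0.936 with a replicate left out) and with the covariate (adjusted p = 9.8e-08). The immediate early list turned to up, and lost its call, when its own score was the covariate (adjusted p = 0.343). Over 54 named genes and 1022 values, 883 kept their side of the threshold, 116 lost a call and 23 gained one. None was called in the opposite direction, and 15 values of genes called in neither fit changed sign. Over 560 list values, 516 were the same, 30 lost a call, 10 gained one and 4 turned. A pair of values not called in either fit counts as the same whatever its sign. Depth limits low genes: of the called genes, Klrg1, Slc7a10 and the predicted gene Gm6637 rest on fewer than 1 CPM in the cKO group.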

Other observations

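All tests of gene families and of explanations below were chosen after the results were seen, except the counts over other splits and the test of shared reads for Wdfy4. Of 18 families defined by gene symbol, 3 were lower with both the preset and an estimated correlation of limma's camera. The 16 chemokine receptors had a median log2 fold change of -0.71 (adjusted p = 0.0089 with an estimated correlation), and adjusted over the family alone 9 were lower, among them the follicular homing receptor Cxcr5 and Ccr1. The 7 S100 proteins (median -0.41, adjusted p = 0.0168) had 4 lower members, and the 4 killer cell lectin-like receptors (median -0.60, adjusted p = 0.0441) had 2, Klrg1 and Klrb1f. Most of the chemokine receptors and S100 genes that were lower also stand in the effector-phenotype list, so these are not separate findings. Nor is the lectin-like family, which was chosen after Klrg1, 1 of its 4 members, had been seen to fall most among called genes. The 30 interleukin receptors were lower with the preset correlation only (adjusted p = 5.6e-05; adjusted p = 0.118 with an estimated correlation), and adjusted over the family alone 8 were lower, including Il9r, Il18r1, Il18rap and Il17rb. Also lower with the preset correlation only were 11 chemokines (median -0.14, adjusted p = 0.0051; adjusted p = 0.198 with an estimated correlation) and 9 members of the TNF superfamily (median -0.35, adjusted p = 0.0293; adjusted p = 0.198 with an estimated correlation), each with 2 members lower over the family alone. Integrins as a family did not pass (23 members, median 0.09, adjusted p = 0.587), although Itgb1 was called lower. Cytosolic ribosomal proteins (77 members, median 0.04, adjusted p = 0.0584) and heat shock proteins (63 members, median -0.03, adjusted p = 0.767) did not pass.

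Gm6637, a predicted gene that begins 11.3 kb after the end of Klrg1 on chromosome 6, was called lower as well (log2 fold change -2.79 ± 0.31 SE, edgeR adjusted p = 0.0449).

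Other splits of the 6 libraries bear on the counts of calls. There are 10 splits into 3 and 3, too few for a share under 0.05. For genes, 2 of the 10 splits gave a result as large: the real split called 27 and the highest other, WT1, WT3 and cKO3 against WT2, cKO1 and cKO2, called 69. For lists, 2 of the 10 gave as many: the real split called 9 and the highest other 13. The split with 69 genes points to a structure of the samples other than genotype, with no batch in the labels to set it against. Of the lists of other cell types, the myeloid and B cell lists follow it. In WT2, cKO1 and cKO2 the mean log2 CPM was 2.48 to 3.16 for the myeloid list and 1.65 to 2.22 for the B cell list, against 1.29 to 1.48 and 0.73 to 1.05 in the other libraries. The stromal, conventional CD4 T cell, plasma cell, and CD8 T and NK cell lists do not follow it. The erythroid list does so by a small margin (0.26 in cKO2 against 0.23 in WT3).

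The lower effector-phenotype and suppressive lists may reflect a smaller share of effector Treg cells or lower expression per cell, which bulk RNA does not separate and which was not tested. More cells without Foxp3 in the cKO sorts were expected to lower Treg-specific genes about as much as the suppressive list. The 18 genes of the identity list taken as Treg-specific had a mean log2 change of -0.1697 ± 0.007 (SE) against -0.711 ± 0.068 for the suppressive list, and the sort required YFP. The 18 were not uniform, from -0.85 for Cd83 to 0.35 for Gpr83, and include Foxp3 and Il2ra, on which the sort selected through YFP and CD25. The mean argues against such cells as the whole cause only as far as these genes are specific to Treg cells. A small share of such cells stays open. Without WT2 and cKO1, the median of the effector-phenotype list was -0.4756 against -0.4751 with all libraries, and its mean score differed by -0.57 ± 0.11 (SE) against -0.60 ± 0.07, which argues against those libraries as the source. With only 4 libraries left, however, both lists lost their call with an estimated correlation (adjusted p = 0.238), though not with the preset one (adjusted p = 6.9e-40 and 1.4e-38).

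Wdfy4 rose by 25.2 ± 2.43 CPM (SE), while the sum of 9 B cell markers, Cd74 and class II MHC left out because other cells also express them, differed by 2.112 ± 5.28 CPM (SE) and was lowest in cKO3. Most of that sum came from Cd22 (8.57 to 5.38 CPM) and Cd79b (9.12 to 7.98 CPM), which fell, while the means of the other markers in it rose, such as Cd79a (1.84 to 3.58 CPM). The sum of all 13 markers was higher in cKO1 and cKO2 (127 and 139 CPM) than in any WT library, and lowest in cKO3 (53.5 CPM). These sums do not decide whether B cells carried into the sort contribute to the rise. Bank1, one of these markers, was higher in all cKO libraries (2.33, 2.89 and 3.68 CPM) than in WT (1.44 to 1.69 CPM), so such cells stay open. The estimated counts of Wdfy4 were whole to within 0.01 in 6 of 6 libraries. Since the origin of the fractions is not known and most values are whole, this does not decide whether reads are shared with a copy of the gene. Wdfy4 lies 2.41 Mb from Tkt on chromosome 14, so a sequence difference carried along with the floxed allele may also act on it. Of 64 tested genes within 5 Mb of Tkt, Tkt and Wdfy4 left out, 8 had an unadjusted p under 0.05 (12.5%, exact Clopper-Pearson 95% interval 5.55% to 23.2%), against 7.69% of the others (one-sided Fisher's exact p = 0.1181), which leaves this explanation and an effect of the knockout open. The shares and p were 18.5% and 0.0528 within 1 Mb (5 of 27 genes), 16.7% and 0.0554 within 2 Mb, and 11.8% and 0.118 within 10 Mb. All 5 such genes within 1 Mb (Colq, Cacna1d, Il17rb, Chdh and Sh3bp5) had lower values in cKO, none of them called. Over all genes tested, 646 of the 991 with an unadjusted p under 0.05 were lower as well. Of the 8 within 5 Mb, 7 were lower and 1 was higher. The higher one was Tmem273 (log2 fold change 0.68 ± 0.24 SE, not called), which lies between Tkt and Wdfy4. Il17rb, Chdh and Cacna1d adjoin each other, and Fisher's test counts them as independent.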
